A study of Drosophila melanogaster with 6 samples.

How the data were processed

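MicroRNA libraries were made from ovaries of 7-day-old flies with the QIAseq miRNA kit, which ligates adaptors to both ends of small RNAs and adds a unique molecular identifier (UMI) during cDNA synthesis, and were sequenced as single-end reads, per the labels' protocols. There were 6 libraries, 2 of each of 3 genotypes (w1118, wh7 and mei-p26), grouped by their labels. bcl2fastq 2.20, Trimmomatic and the BDGP5 genome build are named in the submitters' processing notes, and the aligner, the counting tool and the miRNA annotation are not given in the sources used here. The deposited table held whole-number counts per mature miRNA and precursor in 474 rows, headed raw read counts per the file headers. Whether UMIs were collapsed into these counts is not stated, and PCR copies may therefore be counted as separate molecules. Of 466 mature names, 7 had more than 1 row because they have several precursors, 15 rows in all, and the authors' counts on those rows were the same or close, with the widest gap for miR-2a-3p (1000 and 1115 counts in w1118 replicate 1). Reads that fit several precursors may have been counted on each or divided. The table's control columns are headed W118 per the file headers and were taken as w1118. The authors' CPM values equalled the count over the column total to within 0.00500 and were not used for testing. The authors' deposited signed fold changes, p-values and adjusted p-values compare each mutant with w1118, with a test that is not given in the sources used here, and served for comparison alone.

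The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the deposited counts with TMM scaling. All 6 libraries entered 1 fit with 3 residual degrees of freedom, rows were kept by filterByExpr with a minimum count of 10, and p-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. Of 474 rows, 188 had no count in any library, and 150 rows with 143 mature names were tested, which held 99.9% of counts in every library. Against a group with 0 counts, the fold is a lower bound computed with 3 counts over the group, and with 1 to 3 counts the ratio of summed counts is given with its exact 95% interval. Library totals ran from 144175 to 249262 counts, which limits what can be said of miRNAs with few counts. TMM factors ran from 0.877 to 1.16.

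Fixed lists of miRNAs were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, where at least 3 rows were tested, with adjustment over 15 lists and 3 comparisons. The lists were ovarian germline regulators (bantam, miR-7, miR-184, miR-278, miR-34), the let-7 complex, later-stage follicle cells (miR-318, miR-994, miR-989, miR-279, miR-996), the miR-310s with miR-991, miR-992 and miR-2498, testis-enriched clusters (miR-959 to miR-964, miR-972 to miR-979, miR-303, miR-982 to miR-984), the miR-309 cluster, the miR-2 family, mirtrons, miR-277 with miR-34 (2 of the 3 members of their cluster, without miR-317), and the miR-9c, miR-275, miR-12, miR-998 and miR-92 clusters. Markers were also listed for other tissues, here meaning any beside germline and follicle cells. They were muscle (miR-1, miR-133), nervous system (miR-124, miR-137, miR-210, miR-219) and gut and Malpighian tubule (miR-281). miR-34 and miR-11 are each in 2 lists. Arm ratios were log2 of the 5p over the 3p count with a pseudocount of 1, for precursors with a mean count of at least 10 on each arm, tested with limma. The tests, lists and alternatives were fixed before the data were examined, except where said otherwise. The miRNAs named are, per comparison, the 12 largest rises and 12 largest falls among calls whose libraries do not overlap between groups, the 10 most abundant in w1118, and up to 4 members of each list with the highest mean; any others were chosen after their values were seen.

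The overlap between the mutants was set beside 100 simulated draws of unchanged groups. In each draw all 6 libraries, controls included, were simulated from the mean of each miRNA over the 6 libraries. Both simulated mutants were compared with the same simulated controls. In data simulated for mei-p26 against w1118, 20 of 150 miRNAs were changed by each fold in each of 10 draws. The main test recovered 95.3% of 4-fold and 39.3% of 2-fold changes, and 6.50% of its calls were false. The recovered shares are of changed miRNAs that passed the filter in the simulated counts and leave out those filtered away. Alternatives were RLE, total-count and upper-quartile scaling, no filter, a mean count of at least 50, DESeq2 1.42.0, limma-voom, a replicate block, a fit of only the groups compared, each library left out, a threshold of 0.1, and for lists an estimated correlation and fry; 1 row per mature miRNA and scaling without the 10 most abundant miRNAs were added after seeing the data. The reference annotation at hand was of a later genome release than BDGP5, so no coordinates are given and it served only to find which miRNA genes lie within 10 kb of each other.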

Results

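Small RNA was sequenced from the ovaries of 7-day-old adult *Drosophila melanogaster* of 3 genotypes, each in duplicate. The control was w1118, a white-eyed laboratory strain that is also the genetic background named for the mutants. The wh7 flies carried a mutation of wuho, which encodes a WD40 repeat protein needed in the germline. The mei-p26 flies carried a mutation of mei-P26, which encodes a TRIM-NHL protein that acts with the miRNA pathway in germline cells. The comparisons ask which ovarian miRNAs differ in abundance between each mutant and the control, and between the mutants. The 6 libraries held 152848 and 144175 counts in w1118, 149520 and 228031 in wh7, and 229276 and 249262 in mei-p26. A count of 0 in 1 library allowed up to 3 counts, at most 20.8 CPM, the count relative to the library total, and this floor and the count intervals given here cover counting error only. Replicates correlated across miRNAs, which are not independent replicates, with Pearson's r of 0.981 in w1118, 0.991 in wh7 and 0.979 in mei-p26, and differed by more than sampling noise. The labels do not say that the duplicates came from separate flies, so p-values measure the spread between these libraries, which may be technical. The messenger RNAs of wuho and mei-P26 are not measured by a miRNA library, so the mutations could not be checked in these counts. Values are CPM after TMM scaling, as mean ± SD of 2 libraries, and log2 fold changes are given ± SE. This SE is approximate: it is the size of the log2 fold change over the square root of its quasi-likelihood F statistic.

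In wh7 ovaries, every tested member of the miR-309 cluster was higher than in w1118. This cluster is transcribed from the zygotic genome in early embryos, where it takes part in clearing maternal messenger RNAs. miR-6-3p was at 1725 ± 631 CPM in wh7 and 124 ± 58.5 CPM in w1118, a log2 fold change of 3.79 ± 0.44 (edgeR quasi-likelihood test, adjusted p = 2.27e-06). miR-991-3p, from the group of the miR-310s, was at 467 ± 14.1 CPM against 48.0 ± 27.3 CPM (log2 fold change 3.28 ± 0.40). miR-978 fell. Its 3p arm had 2 counts in the wh7 libraries and 56 in the w1118 libraries, so that it was 37.8 times higher in w1118, with a 95% counting interval of 9.98 to 319. Its 5p arm had 0 counts in wh7 and was at least 7.64-fold higher in w1118 against a floor of 3 counts over the group.

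Of 150 rows tested, 23 passed, 17 higher and 6 lower in wh7, which stand for 20 mature miRNAs because the 3 copies of miR-6 and both copies of miR-281 have rows of their own. Within the miR-309 cluster 6 of 6 rows rose, 6 also when adjusted over the list alone, with a median log2 fold change of 3.79; these rows hold 4 mature miRNAs. miR-286-3p rose by 4.03 ± 0.59 and miR-5-5p by 2.92 ± 0.54 on the log2 scale. miR-3-3p had 67 counts in wh7 and 2 in w1118, a ratio of 24.8 with an interval of 6.61 to 209. The competitive set test (camera) placed this cluster above the other miRNAs with an adjusted p of 4.63e-06, and this call was lost with an adjusted p = 0.597 with an estimated correlation. Camera took the 3 rows of miR-6-3p, which hold nearly the same counts, as separate members, here and in the comparison of the mutants. Its p therefore rests on fewer separate measurements than rows. Other rises were those of miR-274-5p, with 39 counts against 1 and a ratio of 28.9 (4.89 to 1171), and miR-252-5p, with 30 against 1 and a ratio of 22.2 (3.70 to 908). miR-956-3p rose by 2.74 ± 0.63, miR-375-3p by 2.45 ± 0.66 and miR-10-3p by 2.29 ± 0.53. Among miRNAs of higher abundance the falls were smaller. miR-282-3p changed by -1.96 ± 0.53, miR-317-3p by -0.88 ± 0.25, miR-304-5p by -0.85 ± 0.28 and miR-9c-5p by -0.84 ± 0.27. Beside these groups, the muscle marker miR-1-3p was at 23507 ± 719.6 CPM in wh7 and 13858 ± 4202 CPM in w1118 (log2 fold change 0.76 ± 0.25, adjusted p = 0.0386), a call kept under 7 of 17 alternatives. The gut and Malpighian tubule marker miR-281-3p was at 3979.9 ± 415 CPM and 2082 ± 240.1 CPM (0.93 ± 0.28). bantam-3p, which promotes growth and germline stem cell maintenance, had a log2 fold change of -0.48 ± 0.23 (adjusted p = 0.164), let-7-5p of -0.36 ± 0.23 (adjusted p = 0.301) and miR-989-3p, known from border cell migration, of -0.40 ± 0.24 (adjusted p = 0.274). The count was 10 without wh7 replicate 1, 13 without wh7 replicate 2 and 9 among rows with a mean count of at least 50, and scaling by total count gave 17 higher and 3 lower. Without w1118 replicate 2 the split turned to 7 higher and 11 lower, and without w1118 replicate 1 it was 16 and 1. miR-286-3p, the 3 rows of miR-6-3p, miR-991-3p and miR-978-3p passed whichever of the 6 libraries was left out, and the other 17 calls were lost without at least 1 of them. The calls of miR-3-3p and miR-5-5p were lost without wh7 replicate 1. Those of miR-274-5p, miR-252-5p, miR-956-3p, miR-375-3p and miR-10-3p were lost without w1118 replicate 2. miR-252-5p and miR-375-3p were also lost without wh7 replicate 1, and miR-956-3p without wh7 replicate 2. miR-281-3p was lost without either w1118 or either wh7 library, and miR-1-3p without w1118 replicate 2, either wh7 library or mei-p26 replicate 2.

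In mei-p26 ovaries, miR-991-3p rose from 48.0 ± 27.3 CPM in w1118 to 20088 ± 5564 CPM, a log2 fold change of 8.70 ± 0.40 (edgeR quasi-likelihood test, adjusted p = 3.99e-13). Its neighbours miR-992 and miR-2498 and all tested arms of miR-303, miR-982, miR-983 and miR-984 rose with it. In the opposite direction, miR-318-3p, an abundant miRNA of the control ovary, fell from 137868 ± 3982 to 24994 ± 7798 CPM (log2 fold change -2.46 ± 0.26, adjusted p = 1.68e-07). miR-994-5p, encoded beside it, was at 46600.5 ± 15659 CPM in w1118 and 8846 ± 2331 CPM in mei-p26 (-2.40 ± 0.27). Both rows of miR-281-3p, a gut and Malpighian tubule marker, fell to 266 ± 51.0 CPM from 2082 ± 240.1 CPM (-2.96 ± 0.30).

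**Figure D1:**
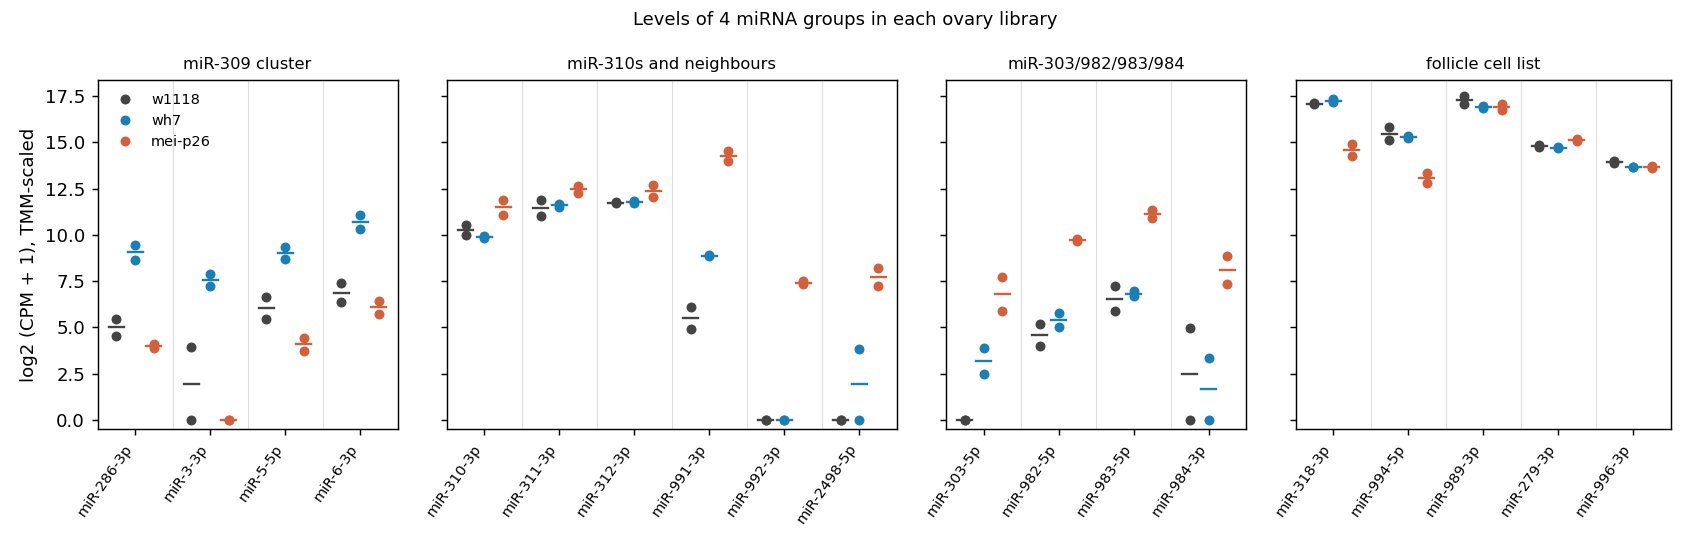
Levels of selected miRNAs of 4 groups in each library, as log2 of TMM-scaled CPM + 1; each point is 1 library, short bars are the means of these log values, and colours mark the genotype. miR-309 cluster members lie highest in wh7, miR-991-3p and the miR-303 group highest in mei-p26, and miR-318-3p lies near 24994 CPM in mei-p26 against 137868 CPM in w1118.

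In all, 51 of 150 rows passed, 32 higher and 19 lower in mei-p26, or 49 mature miRNAs. Upper-quartile scaling gave 22 higher and 25 lower, leaving out w1118 replicate 2 gave 27 and 32, leaving out wh7 replicate 1 gave 20 and 14, and 26 rows passed among those with a mean count of at least 50. The group of the miR-310s had 10 of its 11 tested members higher, 10 also when adjusted over the list alone, with a median log2 fold change of 2.06. miR-310-3p rose by 1.27 ± 0.32, miR-311-3p by 0.97 ± 0.29 and miR-312-3p by 0.69 ± 0.26 on the log2 scale. The call of miR-312-3p was kept under 3 of 17 alternatives. Against 0 counts in w1118, miR-2498-5p was at least 20.5-fold higher, miR-992-3p at least 15.4-fold and miR-991-5p at least 11.6-fold. The camera test gave this list an adjusted p of 2.34e-05, lost with an adjusted p = 0.635 with an estimated correlation. In the testis-enriched list, 8 of 17 tested members rose and 2 fell, with 9 and 2 when adjusted over the list alone (camera adjusted p = 0.00517; adjusted p = 0.718 with an estimated correlation). The risers were the 8 tested rows of miR-303, miR-982, miR-983 and miR-984, which lie together in the genome. miR-983-5p was at 2266 ± 489 CPM against 103 ± 65.1 CPM and miR-982-5p at 836 ± 44.7 CPM against 25.4 ± 14.8 CPM. The 7 tested arms of miR-959 to miR-964, from the same list, had a median log2 fold change of 0.64, and 0 passed with edgeR, DESeq2 or limma-voom, with 2 at an unadjusted p under 0.05. Both arms of miR-978 fell, the 3p arm by -4.12 ± 0.72 on the log2 scale. Both miR-983 copies have a row with the same counts, so that reads fitting both were counted on each or divided evenly. Camera took these rows as separate members of the testis-enriched list.

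Among later-stage follicle cell miRNAs, 3 of 8 tested members fell in mei-p26, 3 also when adjusted over the list alone, namely miR-318-3p and both arms of miR-994. The camera test did not separate this list from the other miRNAs (adjusted p = 0.294). miR-989-3p in the same list had a log2 fold change of -0.40 ± 0.24 (adjusted p = 0.192). miR-279-3p, a regulator of JAK/STAT signalling in border cells, had 0.30 ± 0.22 (adjusted p = 0.297). miR-996-3p was at -0.27 ± 0.22 (adjusted p = 0.358), and its sign turned with scaling by total count. The miR-281 list fell as a whole, 3 of 3 rows, 3 also when adjusted over the list alone (median log2 fold change -2.96, camera adjusted p = 0.00306; adjusted p = 0.597 with an estimated correlation). Because 2 of these rows hold the same counts of miR-281-3p, the list stands for 2 mature miRNAs, and with 1 row for each it would be under the minimum of 3 rows for camera. Of the mirtrons, which are spliced introns processed without Drosha, 3 of 7 tested arms fell and 1 rose, or 3 and 2 when adjusted over the list alone (camera adjusted p = 0.298). The riser over all rows was miR-1007-3p, with 31 counts against 3, a ratio of 5.31 (1.66 to 27.1), and its call was lost without any 1 of the 6 libraries, at up to 0.283, and kept under 3 of 17 alternatives. miR-1012-3p changed by -1.90 ± 0.32 and miR-1012-5p by -1.71 ± 0.39. Among germline regulators 2 of 9 tested arms rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.983). miR-34-5p rose by 0.76 ± 0.25 and miR-184-5p by 1.26 ± 0.44 on the log2 scale, each kept under 9 of 17 alternatives, and miR-7-5p, which acts on the division of germline stem cells, changed by -0.63 ± 0.23. bantam-3p was at -0.22 ± 0.23 (adjusted p = 0.477), with its sign turned by total-count scaling, and let-7-5p at -0.32 ± 0.23 (adjusted p = 0.290). miR-31b-5p fell by 2.80 ± 0.45 on the log2 scale while its close paralog miR-31a-5p rose by 1.66 ± 0.24, and reads of such similar sequences may be split between them. The muscle marker miR-1-3p stood beside all these groups at 24965 ± 3380.0 CPM in mei-p26 and 13858 ± 4202 CPM in w1118 (0.85 ± 0.25, adjusted p = 0.0106), a call lost without w1118 replicate 2, wh7 replicate 1 or mei-p26 replicate 2. Of the 51 calls, 28 passed whichever of the 6 libraries was left out. Those of miR-310-3p, miR-311-3p, miR-34-5p and miR-7-5p were each lost without at least 1 library, at adjusted p of up to 0.0689, 0.245, 0.266 and 0.366.

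Set against each other, the mutants differed in the clusters named above. The miR-309 cluster was lower in mei-p26 than in wh7 in 6 of 6 rows, 6 also when adjusted over the list alone (median log2 fold change -4.83, camera adjusted p = 8.84e-06; adjusted p = 0.597 with an estimated correlation). miR-286-3p changed by -5.12 ± 0.60, and miR-3-3p, with 0 counts in mei-p26, was at least 32.2-fold higher in wh7. miR-991-3p was higher in mei-p26 by 5.42 ± 0.32 on the log2 scale (edgeR quasi-likelihood test, adjusted p = 3.66e-11), and miR-983-5p by 4.33 ± 0.42. miR-318-3p was lower by -2.63 ± 0.26 and miR-281-3p by -3.90 ± 0.31.

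Of 150 rows, 41 passed between the mutants, 19 higher and 22 lower in mei-p26, or 37 mature miRNAs. Among rows with a mean count of at least 50 the count was 26, and 31 of the 41 passed whichever library was left out. In the miR-310s, 9 of 11 tested members were higher in mei-p26, and 11 when adjusted over the list alone (camera adjusted p = 4.63e-06; adjusted p = 0.597 with an estimated correlation). The testis-enriched list had 7 of 17 members higher, 8 when adjusted over the list alone (camera adjusted p = 0.000104; adjusted p = 0.597 with an estimated correlation). miR-984-3p had 173 counts in mei-p26 and 2 in wh7, a ratio of 59.9 with an interval of 16.3 to 499. The miR-281 list, with miR-281-3p counted on 2 rows, had 3 of 3 rows lower, 3 also when adjusted over the list alone (camera adjusted p = 0.00152; adjusted p = 0.597 with an estimated correlation). Of the follicle cell list 3 of 8 were lower, 3 also adjusted over the list alone (camera adjusted p = 0.294), and of the mirtrons 2 of 7, 2 also adjusted over the list alone (camera adjusted p = 0.434). miR-31b-5p was lower by -3.03 ± 0.44, and miR-956-3p by -4.64 ± 0.69. The muscle marker miR-1-3p did not separate the mutants (log2 fold change 0.09 ± 0.24, adjusted p = 0.852).

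Changes against w1118 were shared in the same direction by 10 miRNAs, 6 higher and 4 lower in both mutants. The shared rises were those of miR-991-3p, miR-274-5p, miR-252-5p, miR-9a-5p, miR-31a-5p and miR-1-3p, and the shared falls those of both arms of miR-978, miR-282-3p and miR-304-5p; all 10 are named because they make up the count. miR-991-3p and miR-978-3p passed in both mutants whichever library was left out, and the other 8 did not. miR-282-3p was at 1562 ± 1013 CPM in w1118 (2278 and 846 in its libraries) and 599.9 ± 535 CPM in mei-p26, whose higher library lay above the lower of w1118. Its calls were lost without w1118 replicate 1 or wh7 replicate 1 in both mutants, and without mei-p26 replicate 1 in mei-p26, at adjusted p of up to 0.320 in wh7 and 0.421 in mei-p26. miR-9a-5p rose by 1.58 ± 0.35 in wh7 and by 1.83 ± 0.35 in mei-p26. The rise of miR-991-3p differed between the mutants (adjusted p = 3.66e-11), as did that of miR-31a-5p (adjusted p = 0.0231, lost without w1118 replicate 1, either wh7 replicate or mei-p26 replicate 2). Independent lists of these sizes would share 4.39, a value that leaves out the shared controls. Unchanged groups, with all 6 libraries simulated from their common mean and the same simulated controls for both mutants, shared 0 in 100 draws. They had at most 2 calls in a comparison, so this does not show what shared controls add where groups do change. The same sign was seen in 68.0% of rows, against 67.8% in the simulation. The log2 fold changes of both mutants correlated across miRNAs with r = 0.350, against a simulated mean of 0.536 from the shared controls alone. Their covariance was 1.17 against a simulated 0.103, an excess of 1.07. Rows with large fitted changes in both mutants weigh most in it. Among them are miR-991-3p (3.28 in wh7 and 8.70 in mei-p26), miR-978-5p (-6.62 and -3.85) and miR-274-5p (4.62 and 5.14). Values of rows with few counts in a group, such as the last 2, depend on the prior count. The simulation gave every group the same mean, so it does not show what such rows add, and no conclusion is drawn from the excess. The controls were not split, since each part would hold 1 library, and part of the overlap may come from the shared controls. Shared effects of the mutations also cannot be told apart from other differences between the w1118 flies and both mutant lines. miR-5-5p and both rows of miR-281-3p changed in opposite directions. The overlap was 4 without wh7 replicate 1, 5 without wh7 replicate 2, 11 without w1118 replicate 2 (4 of them among the 10 above), 6 with DESeq2 and 3 among rows with a mean count of at least 50.

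**Figure D2:**
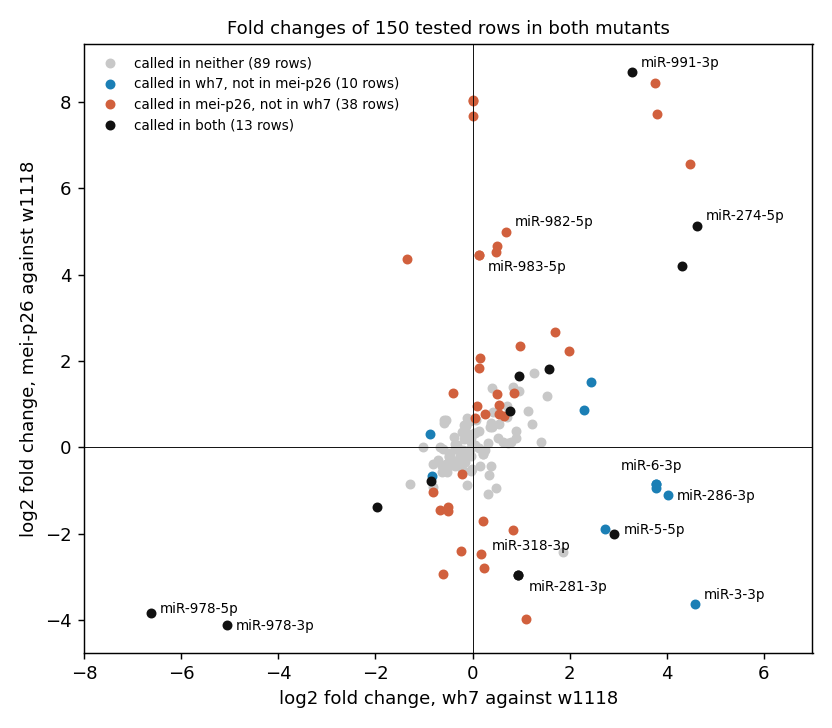
Fitted log2 fold changes of the 150 tested rows in wh7 (x axis) and mei-p26 (y axis), each against w1118; colours mark in which comparison a row passed the adjusted threshold. miR-991-3p lies at 3.28 and 8.70, and miR-281-3p at 0.93 and -2.96; values of rows with 0 to 3 counts in a group, such as miR-978-5p and miR-3-3p, depend on the prior count.

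The remaining 37 list comparisons did not pass the camera test, with adjusted p from 0.157 to 0.983. In wh7, none of 9 germline regulator arms, 5 arms of the let-7 complex, 8 follicle cell arms, 14 arms of the miR-2 family, 7 mirtron arms, 4 arms of miR-277 and miR-34, 4 of the miR-275 cluster, 4 of the miR-998 cluster or 3 of the miR-92 cluster passed, over all rows or adjusted over the list alone. Some rows are in several lists. The miR-2 family list held miR-2a, miR-2b, miR-2c, miR-11, miR-13a, miR-13b and miR-308. It did not hold miR-6, which was listed with the miR-309 cluster and whose 3p rows rose in wh7. The list of miR-277 and miR-34 leaves out their neighbour miR-317, whose 3p arm was lower in wh7 (-0.88 ± 0.25, lost without w1118 replicate 1 or either wh7 replicate, at adjusted p of up to 0.407) and higher in mei-p26 than in wh7 (1.20 ± 0.25, adjusted p = 0.000628, lost without wh7 replicate 2 at 0.0757). Of the 54 distinct rows, 4 had an unadjusted p under 0.05 with edgeR, and 0 passed with DESeq2 or limma-voom. The miR-9c cluster had 1 of 6 arms lower (camera adjusted p = 0.157) and the miR-12 cluster 1 of 6 (0.289), both also adjusted over the list alone. The miR-310s had 1 of 11 higher (0.983) and the testis-enriched list 2 of 17 lower (0.808), each with the same count adjusted over the list alone. The miR-281 list had 2 of 3 rows higher, both with the same counts of miR-281-3p, and 3 adjusted over the list alone (camera adjusted p = 0.185). In mei-p26 against w1118, the let-7 complex had 1 of 5 arms higher and 0 adjusted over the list alone, miR-125-5p at 0.77 ± 0.29 (kept under 6 of 17 alternatives). The miR-309 cluster had 1 of 6 rows lower and 0 adjusted over the list alone (camera adjusted p = 0.157), the miR-12 cluster 1 of 6 lower and 0, and the list of miR-277 and miR-34 1 of 4 higher and 1, which was miR-34-5p. None of the 29 rows of the miR-2 family and the miR-9c, miR-275, miR-998 and miR-92 clusters passed there, nor with DESeq2 or limma-voom, with 3 at an unadjusted p under 0.05. Between the mutants, 1 of 4 arms of the miR-998 cluster was lower, also adjusted over the list alone, and none passed in the germline regulators, the let-7 complex, the miR-2 family, the list of miR-277 and miR-34, the miR-9c, miR-275, miR-12 and miR-92 clusters or the muscle list, nor with DESeq2 or limma-voom. Of those 51 distinct rows, muscle included, 3 had an unadjusted p under 0.05. The lone calls of the miR-9c, miR-12, miR-309, miR-998, let-7 and miR-277 lists given here were each lost without wh7 replicate 1 and without at least 2 further libraries in turn, at adjusted p of up to 0.675. The camera direction was opposite to both median and mean in wh7 for the germline regulators, the miR-310s and the mirtrons, and in mei-p26 against w1118 for the miR-275 cluster. Median and mean differed in sign in wh7 for the follicle cell list, the testis-enriched list and the miR-2 family, and between the mutants for the miR-9c cluster. Medians did not move when members at 0 counts were set to their bounds. Of the markers of other tissues, the muscle list had 1 of 2 arms higher in each mutant against w1118, also adjusted over the list alone, and 0 between the mutants. Both tested arms were of miR-1. The other muscle marker, miR-133-3p, had 1 to 3 counts per library and was not tested, so the muscle calls rest on miR-1-3p alone. Nervous system miRNAs summed to between 1 and 8 counts per library and were not tested.

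The 10 most abundant miRNAs of the control ovary, led by miR-989-3p at 161457 ± 32969 CPM and miR-318-3p, took 67.6 ± 0.970% of counts in w1118, 65.1 ± 1.13% in wh7 and 56.3 ± 1.87% in mei-p26. miR-318-3p alone took 12.7 ± 1.26%, 15.2 ± 1.20% and 2.75 ± 0.700%. These shares were not tested, and an exact two-sided test of 2 libraries against 2 gives no p under 1 in 3. miR-276a-3p, also of the 10, rose in mei-p26 by 0.72 ± 0.26 on the log2 scale, a call lost without w1118 replicate 1, either wh7 replicate or mei-p26 replicate 2. The ratio of 5p to 3p arms was tested with limma in 50 precursors and 3 comparisons, and 2 of 150 tests passed, both for mir-991 against w1118 (adjusted p = 0.0111 in wh7 and 0.00583 in mei-p26). The 5p arm had 0 counts in w1118 and in wh7, where the ratio is set by the pseudocount of 1. Neither call was left with a replicate block, without w1118 replicate 1, without either mei-p26 replicate or with at least 50 mean counts per arm. At an unadjusted p under 0.05, 24 of the 150 tests passed.

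In the authors' deposited table, 21 rows had an adjusted p under 0.05 for wh7 against w1118, 14 higher and 7 lower. Of these, 20 were also called here in the same direction, and 3 further rows were called here alone. For mei-p26 against w1118 the authors' deposited table had 31 such rows, 19 higher and 12 lower, all 31 called here in the same direction beside 20 further rows.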

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

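The edgeR comparisons in this part were planned, and the tests of explanations for the miR-309 cluster were chosen after the results they bear on had been seen. miRNAs that changed against w1118 in opposite directions in the mutants, with the difference between the mutants tested directly, are reported here. miR-281-3p, in both of its rows, was at 0.93 in wh7 and -2.96 in mei-p26 (log2 fold change), and the mutants differed by -3.90 (edgeR, adjusted p = 3.31e-09). miR-281 had been listed beforehand as the marker of gut and Malpighian tubule, and how much of these tissues each dissection held was not measured, so the values do not separate a change in the ovary from carried-over tissue. The rise of miR-281-3p in wh7 was lost without either w1118 or either wh7 library, at an adjusted p of up to 0.261.

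miR-5-5p was at 2.92 in wh7 and -2.01 in mei-p26, and the mutants differed by -4.93 (edgeR, adjusted p = 9.00e-07). It had 13 and 6 counts in the w1118 libraries, 96 and 92 in wh7, and 3 and 6 in mei-p26. The fall in mei-p26 thus rests on few counts. In the authors' deposited table, and adjusted over the miR-309 list alone, miR-5-5p did not pass as lower in mei-p26. Its rise in wh7 was lost without wh7 replicate 1 (adjusted p = 0.0539), and its fall in mei-p26 without w1118 replicate 1, wh7 replicate 1 or either mei-p26 replicate, at up to 0.274.

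The rise of the miR-309 cluster in wh7, of which miR-5 is a member, was weighed against technical explanations. A difference in depth is argued against for the 6 called rows. They lay above both w1118 libraries (152848 and 144175 counts) in wh7 replicate 1 too, which held 149520 counts. With every library thinned to 144175 counts, 6 of the 6 called rows still passed in each of 10 draws. Among the libraries of wh7 and w1118 this mainly changed wh7 replicate 2, which held 228031 counts, so the thinning is a weak test here. Early embryos or activated eggs left in the dissected ovaries cannot be told apart from an effect of the genotype. Of 9 tested arms of other early-embryo miRNAs, 4 were higher in wh7, but 3 of these were higher in mei-p26 too, where the cluster did not rise, which leaves 1, miR-10-3p (log2 fold change 2.29); miR-1-3p, at 23507 CPM the most abundant of them, is also a muscle miRNA. An effect of wuho on the ovary stays open and untested, as does any difference between fly lines other than the mutation.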

How the results depend on the processing

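The replicate numbers did not pair the samples (correlations of same-numbered deviations -0.33 for w1118 and wh7, -0.02 for w1118 and mei-p26, 0.09 for wh7 and mei-p26); a replicate block gave 26, 50 and 41 calls for wh7 and mei-p26 against w1118 and mei-p26 against wh7, 14 shared, 8 lists and 0 arm ratios.

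Of 95 named results 86 were called, and 53 of these were kept under each of the 17 alternatives in which they were tested. Of the 39 tested in all 17, 23 were kept in all. Rows with a mean count of at least 50, of which fewer were tested, gave 9, 26 and 26 calls, 3 shared, and 0 arm ratios. DESeq2 gave 6 shared. An estimated correlation left 0 lists (1 at an unadjusted p under 0.05), and fry, which does not compare a list with others, passed 13. With 1 library left out, and the lone sample assumed to vary like the other groups, calls ran from 10 (without wh7 replicate 1) to 30 for wh7, with 13 without wh7 replicate 2, from 34 to 59 for mei-p26 and from 34 to 55 between mutants. Shared calls ran from 4 (without wh7 replicate 1; 5 without wh7 replicate 2) to 11, lists from 8 to 9 and arm ratios from 0 (without w1118 replicate 1 or either mei-p26 replicate; 1 without wh7 replicate 2) to 3. Without w1118 replicate 2, calls split into 7 higher and 11 lower in wh7 and 27 and 32 in mei-p26. No call changed direction in these fits. With total-count scaling, bantam-3p in mei-p26 turned from -0.22 to 0.0546 and miR-996-3p from -0.27 to 0.00226, where that scaling moved the median of all miRNAs by 0.27; upper-quartile scaling moved it by -0.22. The cause of the other changes was not tested. The planned contrast of reads with UMI counts was not run, since the table holds 1 kind of count. Depth limits miRNAs near the floor of 3 counts, and most 2-fold changes could be missed, as 39.3% were recovered in simulation.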

Other observations

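The edgeR comparisons and the fits with a library left out were planned, and the other tests and the choice of these miRNAs came after the results they bear on had been seen. miR-314 and miR-956, whose genes lie within 10 kb of each other, were both lower in mei-p26 than in wh7. miR-314-3p had 47 counts in wh7 and 3 in mei-p26, a ratio of 22.6 with a counting interval of 7.28 to 114, and miR-956-3p was at 244 ± 94.2 CPM in wh7 against 8.99 ± 6.91 CPM in mei-p26. Against w1118, miR-314-3p did not pass in either mutant (adjusted p = 0.0973 in wh7 and 0.0819 in mei-p26). miR-956-3p was higher in wh7 (log2 fold change 2.74 ± 0.63, adjusted p = 0.00408, lost without w1118 replicate 2 or wh7 replicate 2 at up to 0.0930) and did not pass in mei-p26 (adjusted p = 0.104).

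Within the group of the miR-310s, levels moved by very different amounts. The CPM values of this paragraph are before TMM scaling and relative to the library total with 1 row per mature miRNA. Summed over mature miRNAs, miR-991, miR-992 and miR-2498 held 60.4 and 28.6 CPM in the w1118 libraries, 464 and 496 in wh7, and 27366 and 20098.5 in mei-p26. miR-310 to miR-313 held 6561 and 9917 CPM in w1118, 8731 and 8669 in wh7, and 22968 and 16539 in mei-p26. The testis-enriched miR-972 to miR-979 without miR-978 held 4 and 4 counts in w1118, 2 and 1 in wh7, and 4 and 17 in mei-p26.

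The rise of miR-303, miR-982, miR-983, miR-984 and the neighbours of miR-991 in mei-p26 was weighed against technical explanations. A difference in depth is argued against for the 13 called rows, which include both rows of miR-983-5p. With every library thinned to 144175 counts, 11 of the 13 still passed as the median of 10 draws, and never fewer than 10. Between mei-p26 and w1118 this mainly changed the mei-p26 libraries, which held 229276 and 249262 counts. The rows were picked because they had passed, so the thinning bears on depth alone. Testis tissue among the dissected ovaries cannot be told apart from an effect of the genotype, since no testis library sets the level its other miRNAs would reach. The 7 tested arms of miR-959 to miR-964 had a median log2 fold change of 0.64 with an SD of 0.60, where the 8 rows of the miR-303 group had 4.60, or 4.45 with members at 0 counts set to their bounds. An effect of mei-P26 on these miRNAs, or of another difference between the fly lines, stays open and untested.

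The fall of miR-318 and miR-994 in mei-p26 was weighed in the same way. The fall did not hinge on which of 5 scalings was used, as the log2 fold change of miR-318-3p was at most -2.21 under each. All 5 start from the miRNA counts of a library and differed little. They therefore cannot show a change in the total miRNA of an ovary, and no conclusion on that is drawn. Fewer follicle cells of every kind would lower the other miRNAs of that list by about as much, if follicle cells were their only source. That source was not tested. The 5 tested arms of miR-989, miR-279 and miR-996 had a median log2 fold change of 0.30 with an SD of 0.67. Their abundant 3p arms were at -0.40, 0.30 and -0.27, in that order, and the 5p arms of miR-989 and miR-996 at 1.20 and 0.71. Without w1118 replicate 2, miR-989-3p passed as lower at -0.90 and miR-996-3p at -0.63, still less than the fall of miR-318-3p. A loss of some follicle cell stages and an effect of the genotype on these miRNAs stay open, and neither was tested.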
